A study of Mus musculus with 5 samples.

How the data were processed

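The series held 20 tables, 4 for each of 5 mouse libraries, with 1 library per cell type. Oocytes and zygotes came from superovulated C57BL6 females and were freed of cumulus cells and zona, per the labels' protocols. Primordial germ cells were isolated with anti-CD15 beads and spermatogonia by letting somatic cells settle and adhere for some hours. Spermatozoa from cauda epididymis and vas deferens of CD-1 males were taken through a density gradient and a hypo-osmotic shock meant to remove other cells. Primordial germ cells and spermatogonia were also from CD-1 mice, so the strain differs between the male germ cell and the egg libraries. Per the labels, spermatogonia were checked for Stra8 and for the absence of Fn1, a somatic gene. Total RNA was extracted with TRIzol and sequenced on Illumina instruments, with reads of 18 to 32 nucleotides, per the labels' protocols. Bowtie 0.12.7, DESeq and the mm10 genome are named, without their roles, per the submitters' processing notes. Annotation sets, mismatches allowed and the treatment of reads with several matches are not given in the sources used here.

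Each table lists an entry name, a read number and a normalised value. The read numbers are expected counts as deposited, since many are not whole. In primordial germ cells 14.8% of miRNA and 80.0% of piRNA values had a fraction, as reads shared between entries would give. In spermatogonia 0% of miRNA but 81.8% of piRNA values had one, for a reason not given. For miRNAs the other libraries had 13.1% to 17.7%. Ratios of miRNAs with spermatogonia may carry this difference. The normalised column is, per the file headers, a TMM value. In the deposited tables it is a signal equal to the reads times 1 factor per library: 0.979 in primordial germ cells, 0.672 in spermatogonia, 1.35 in spermatozoa, 0.937 in the oocyte and 1.37 in the zygote. The read column was used, and that factor only as an alternative. An entry absent from a library's table was taken as 0 reads. The tables hold no sequences, lengths or positions of reads, so read length, first base, and counting identical sequences once were not analysed here. No entry names occur more than once per table. Neighbouring piRNA and endo-siRNA entries often carry near-equal reads, as overlapping or repeated loci would. The endo-siRNA names give no source genes or repeats, so the lists fixed for these were not used.

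Among the snoRNA entries, 6 name no single snoRNA and were left out of totals: they held 0.551% of the snoRNA file's reads in primordial germ cells, 0.824% in spermatogonia, 0.896% in spermatozoa, 3.21% in the oocyte and 4.59% in the zygote. The other 186 were used.

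Reads were scaled to the total of the same class in the library (RPM). Log2 ratios used a pseudocount of 0.5 reads, for entries with at least 100 reads over the pair, and entries at least 4-fold apart were counted. With 1 library per group no test, p-value or SD between cell types is possible. Shares have exact (Clopper-Pearson) 95% intervals, and ratios the exact interval of 2 Poisson counts conditional on their sum, after rounding to whole reads. PCR copies are not independent molecules, so these cover counting error only. Against 0 reads a fold is a lower bound computed from 3 counts in that library. That floor was 0.250 RPM for miRNAs in primordial germ cells and 2.47 in spermatozoa, and for endo-siRNAs 2.19 in spermatozoa and 0.0975 in the zygote.

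The 9 miRNA lists, 9 lists of markers of other cell types, the snoRNA lists and the rule for named entries were fixed before the data were examined. For each list with at least 3 measured members the median log2 ratio was set against 10000 random lists of the same size, matched in 10 bins of mean expression, as a description of these libraries. A list outside percentiles 2.5 to 97.5 is said to stand apart. A scaling factor moves all ratios of a comparison alike, so it leaves these percentiles as they are by construction. Named by rule were the 8 miRNAs with the highest and the 8 with the lowest ratios of each comparison, 2 and 2 for the other classes, the 5 most abundant entries of each class and library, and list members. The comparisons were zygote with oocyte, zygote with spermatozoa, spermatozoa with oocyte, spermatogonia with primordial germ cells, and spermatozoa with spermatogonia. Precursor positions were taken from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, by gene name.

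Tried as alternatives were reads scaled to all 4 classes together, edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors computed on rounded reads, totals without the 5 most abundant entries of each library, minimums of 20 reads and 1 read, and a pseudocount of 5. For these totals and for class shares, the 5 most abundant entries of each library were pooled. That whole set was left out of every library. Chosen after seeing the data were the deposited factor, counting runs of consecutive entries within 10% of their neighbour once, and requiring the whole counting interval beyond 4-fold. Runs left 84.1% of piRNA and 89.8% of endo-siRNA entries. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.

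The steps were tested on simulated counts for zygote and oocyte with 200 changed entries. For 33276 endo-siRNAs, all simulated 8-fold and 16-fold changes and no 2-fold change were called 4-fold, and none of 33099 unchanged entries. For 288 miRNAs, of which only 101 were unchanged, the changes fell on abundant miRNAs and shifted each log2 ratio by -1.48. Scaled to the class total, 46.8% of 2-fold changes were then called 4-fold and only 47.9% of 8-fold changes were, and 0.99% of unchanged miRNAs were called. With the known shift added back, no 2-fold and all 8-fold changes were called. Counts of higher and lower entries can therefore not be read apart from the scaling. The simulation changed far more miRNAs than differed here, where 6 of 299 were at least 4-fold higher and 4 lower in the zygote than in the oocyte. Other scalings shifted that comparison by -0.054 to 0.755. Of 400 unchanged random lists of 10 miRNAs, 6.25% fell outside percentiles 2.5 to 97.5, where 5% would by chance.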

Results

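Small RNAs of 18 to 32 nucleotides were sequenced from 5 kinds of mouse cell: primordial germ cells of 13.5-day fetal testes, spermatogonia of 8.5-day-old testes, spermatozoa from the cauda epididymis and vas deferens, ovulated oocytes, and zygotes. There was 1 library per cell type, so no difference between cell types has a replicate check and no test between them was made. The oocyte library came from 15210 cells and the zygote library from 15416, taken 15 to 18 hours after fertilization. Each library was reported as 4 tables of estimated read counts, for miRNAs, snoRNAs, piRNAs and endogenous small interfering RNAs (endo-siRNAs). The 4 tables held 26563078 reads in primordial germ cells, 26344449 in spermatogonia, 21827067 in spermatozoa, 43242109 in oocytes and 43231608 in zygotes. Levels of miRNAs are given in RPM, the reads of an entry scaled by the total of its class in the library. Brackets after a ratio or share give its exact 95% interval, which covers counting error only. List members are called measured in a comparison where they have at least 100 reads over the pair.

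The male germ line and the egg differed first in which of the reported classes of small RNA took most reads. Shares are over the reads of the reported tables only, and a class is the table an entry was listed in. Without read sequences or lengths, whether the reads are small RNAs of that class was not tested. MicroRNAs took 45.2% of the reads in primordial germ cells and 40.5% in spermatogonia, but 5.57% in spermatozoa, 4.65% in the oocyte and 5.38% in the zygote. In spermatozoa, entries listed as piRNAs, a class known to guide PIWI proteins in the germ line, took 83.4%, against 27.1% in spermatogonia. Of these spermatozoal piRNA reads, 53.7% fell on the 5 most abundant entries. Without all entries that were among the 5 most abundant of their class in any library, the piRNA share in spermatozoa was 82.9%. In the oocyte 60.1% of reads and in the zygote 71.2% fell on entries listed as endo-siRNAs, against 6.28% in spermatozoa. Endo-siRNAs are known as a class cut by Dicer from long double-stranded RNA. The snoRNA share fell from 28.3% in primordial germ cells and 19.4% in spermatogonia to 4.71% in spermatozoa, 1.73% in the oocyte and 1.37% in the zygote. With runs of near-identical piRNA and endo-siRNA entries counted once, the piRNA share in spermatozoa was 79.3% and the endo-siRNA share 64.2% in the oocyte and 72.8% in the zygote. Without the entries among the 5 most abundant of their class in any library, the piRNA share in primordial germ cells was 42.9% in place of 21.9%. The snoRNA shares were then 1.15% there and at most 0.694% in the other libraries. The miRNA share was then 2.01% in the oocyte and 2.35% in the zygote, and the endo-siRNA share 12.1% in spermatozoa, 10.3% in primordial germ cells (4.58% with them) and 23.6% in spermatogonia (13.0% with them).

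**Figure D1:**
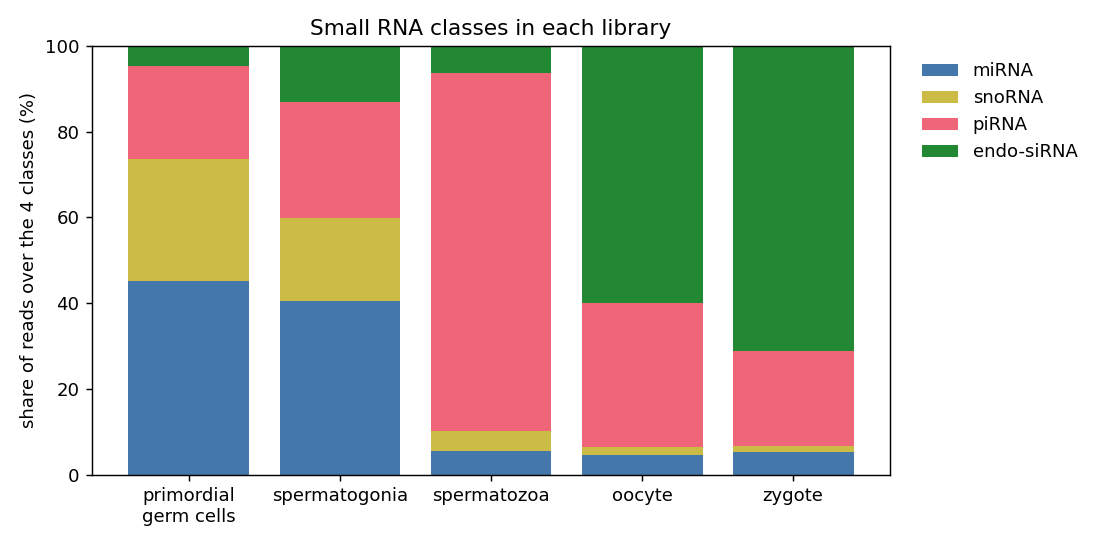
Stacked bars give the share of reads (%, vertical axis) of miRNA, snoRNA, piRNA and endo-siRNA in each of the 5 libraries, over the sum of the 4 classes. The piRNA part is 83.4% in spermatozoa, and the endo-siRNA part is 60.1% in the oocyte and 71.2% in the zygote.

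The zygote was compared with the oocyte and with spermatozoa to see which gamete its small RNAs resembled. Strain and preparation differ between spermatozoa and the egg libraries, so neither can be told apart from cell type. Few miRNAs differed between zygote and oocyte. Among those with at least 100 reads over the pair, 6 (2.01%) were at least 4-fold higher and 4 (1.34%) at least 4-fold lower in the zygote. The higher ones were miR-410-3p at 9.64-fold [7.23 to 13.1], miR-3473b, miR-3473e, miR-215-5p, miR-29b-3p and miR-31-5p at 4.46-fold [4.30 to 4.63]. The lower ones were miR-147-5p at 6.78-fold [6.23 to 7.40], miR-375-3p, miR-1957b and miR-34b-3p. With the factor of the deposited normalised column the split was 16 higher and 1 lower, since that factor raises each zygote/oocyte log2 ratio by 0.76.

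Both egg-stage libraries were led by let-7f-5p, which took 12.2% of oocyte and 14.8% of zygote miRNA reads, by miR-3471 with 14.5% and 14.4%, and by miR-182-5p with 15.9% and 10.3%. The let-7 family, regulators of differentiation timing, summed to 207491 RPM in the oocyte and 240778 in the zygote, and none of its 14 measured members differed 4-fold. In the miR-290 cluster (miR-290 to miR-295), known from embryonic stem cells and the early embryo, none of 12 measured members differed 4-fold. Within it miR-291a-3p (chromosome 7, 3218919 to 3219000, outside other annotated genes on its strand) was 3.54-fold higher in the zygote [3.41 to 3.68]. The miR-34b/c and miR-449 list lay lower in the zygote, with a median log2 ratio of -1.11 over 4 measured members, at percentile 0.84 of 10000 random lists of matched expression. With a minimum of 20 reads that median was -0.60 and the list no longer stood apart. The X-linked testis, Sfmbt2, Dlk1-Dio3, miR-17/92 and miR-30 lists lay between percentiles 52.6 and 95.4.

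Between the zygote and spermatozoa, 81 of 308 miRNAs were at least 4-fold higher in the zygote and 79 at least 4-fold lower. miR-3471 was 3120-fold higher in the zygote [2403 to 4131] and miR-291a-3p 1010-fold [490 to 2513]. All 10 measured members of the miR-290 cluster were at least 4-fold higher, with a median log2 ratio of 7.15, or 6.29 with members at 0 reads set to 3 counts. Spermatozoa had 80 reads over all 14 members. In each comparison with spermatozoa, members of this cluster therefore passed the minimum of 100 reads through the other library, which by itself favours such calls. In the other direction, miR-34c-5p, a miRNA of the later stages of spermatogenesis, was 41.4-fold higher in spermatozoa [40.6 to 42.1], and all 5 measured of the 8 members of its list were at least 4-fold higher there (median -6.89, percentile 0.22). miR-7210-5p was at least 477-fold higher in spermatozoa, with 748 reads there and none in the zygote. All 9 measured of the 74 members of the Sfmbt2 intron cluster were at least 4-fold lower in the zygote, among them miR-466f-3p at 1339-fold [523 to 3764]. The miR-30 family lay higher in the zygote (median 1.69, percentile 97.54). By median, marker lists of other cell types were lower in the zygote as well: erythroid (-5.93, percentile 0.16), leukocyte (-5.11, 0.74) and epithelium (-4.22, 0.09). Of measured members 4 of 4, 4 of 5 and 4 of 6 were at least 4-fold lower, and 1 leukocyte member was at least 4-fold higher. Sums differed less for leukocyte (1631 RPM in the zygote, 3106 in spermatozoa) and epithelium (9929 and 22968). The neuron list did not stand apart (-0.88, percentile 42.04). Scaling moved the balance of this comparison: edgeR's TMM factors gave 100 higher and 56 lower, and the deposited factor 105 and 48, with every log2 ratio raised by 0.66 and 0.96.

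Of 300 miRNAs, 80 were at least 4-fold higher and 79 at least 4-fold lower in spermatozoa than in the oocyte. miR-34c-5p made up 22.2% of spermatozoal miRNA reads and was 27.2-fold higher than in the oocyte [26.8 to 27.7]. By the GRCm38 annotation its precursor lies on chromosome 9 at 51103034 to 51103110 and that of miR-34b beside it at 51103562 to 51103645, both outside other annotated genes on their strand. miR-449a, of the same list, lies in an intron of Cdc20b on chromosome 13 at 113037534 to 113037624, and its 5p arm was 89.9-fold higher in spermatozoa [72.0 to 113.8]. All 8 measured members of the Sfmbt2 cluster were at least 4-fold higher in spermatozoa (median 4.10, percentile 99.85). Higher in the oocyte were miR-3471 at 3141-fold [2418 to 4158], miR-182-5p at 31.1-fold [30.3 to 31.9] and all 11 measured members of the miR-290 cluster (median -6.97, or -5.92 with 0 reads set to 3 counts). Marker lists of other cell types were also higher in the spermatozoa library. The erythroid list had a median of 5.68 (percentile 99.78), with miR-451a at 112.5-fold, and 5 of 7 measured epithelium members were at least 4-fold higher (median 3.24, percentile 99.64). Of 5 measured leukocyte members 4 were at least 4-fold higher, among them miR-142-3p at 119-fold [86.7 to 167], and 1 at least 4-fold lower (median 6.87, percentile 99.89), and the sum of the list was 2.20-fold higher.

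Across miRNAs, the Spearman correlation of the zygote was 0.959 with the oocyte and 0.496 with spermatozoa, over 342 miRNAs, which are not independent replicates. Entries of each class were taken by their reads summed over zygote, oocyte and spermatozoa. That choice by itself can lower the correlation of unlike libraries. For snoRNAs the correlations were 0.923 and 0.431, for piRNAs 0.863 and -0.254, and for endo-siRNAs 0.899 and 0.031. The last was -0.018 with a minimum of 20 reads, and -0.148 as a Pearson correlation of log2 values.

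**Figure D2:**
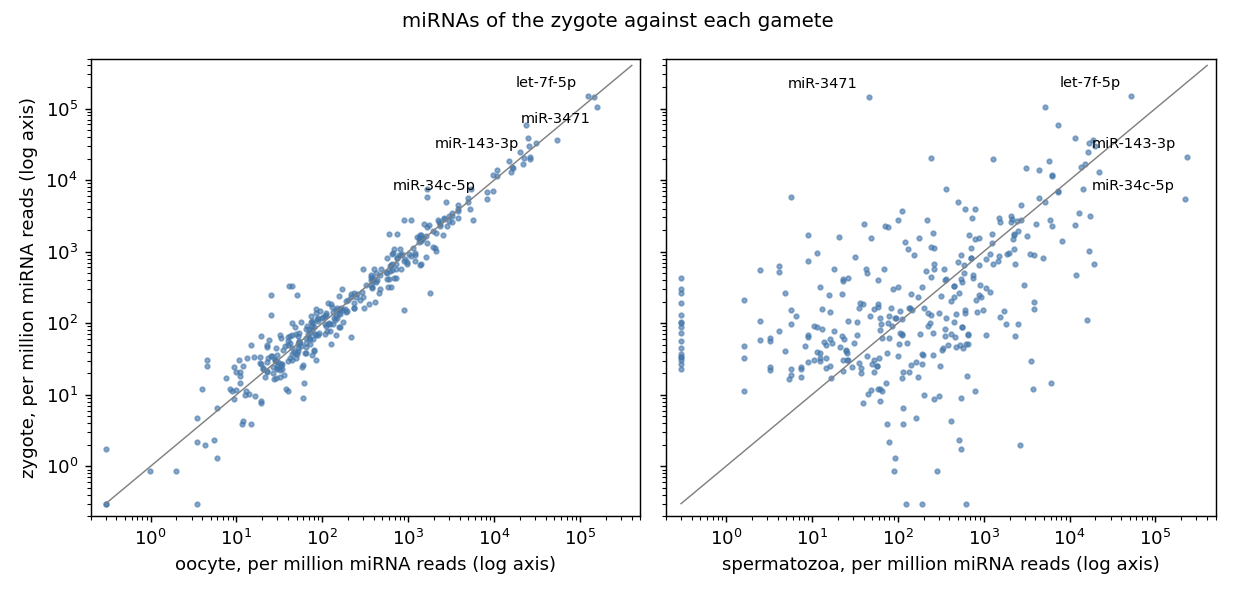
Each point is 1 of 342 miRNAs, with its level in the zygote (vertical, log axis, RPM) against the oocyte (left) and spermatozoa (right). Levels of 0 reads are drawn at 0.3, and the line marks equal levels. The correlation was 0.959 on the left and 0.496 on the right.

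Entries seen in spermatozoa and not in the oocyte were then looked for in the zygote. Of 112 endo-siRNAs with at least 100 RPM in spermatozoa and no read in the oocyte, 22 had a read in the zygote, or 19.6% [12.7 to 28.2]. Of 90 control endo-siRNAs of spermatogonia or primordial germ cells, absent from oocyte and spermatozoa alike, 16 had one, or 17.8% [10.5 to 27.3]. An excess of spermatozoal endo-siRNAs in the zygote was thus not detectable at this depth. The intervals of these shares take entries as independent. Neighbouring entries often carry near-equal reads, so the intervals may be too narrow. Of the oocyte-specific endo-siRNAs, 100% were seen in the zygote [97.2 to 100]. Of the 3 spermatozoa-specific miRNAs, miR-144-3p is on the erythroid and miR-142-5p on the leukocyte marker list. Of these 3, 1 had a zygote read (miR-144-3p, with 4 reads), as had 6 of 6 oocyte-specific miRNAs. For piRNAs it was 3 of 4 spermatozoa-specific, 1 of 1 control and 15 of 15 oocyte-specific ones. With 20 RPM in place of 100, it was 21 of 78 spermatozoa-specific piRNAs (26.9% [17.5 to 38.2]) and 7 of 17 controls (41.2% [18.4 to 67.1]), and 18.5% of spermatozoa-specific and 20.98% of control endo-siRNAs.

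In male germ cell development, spermatogonia were compared with the primordial germ cells that precede them. Of 530 miRNAs, 25.7% were at least 4-fold higher and 12.6% at least 4-fold lower in spermatogonia. The let-7 family was higher in 15 of 16 measured members by at least 4-fold (median 3.80, above the 10000 random lists), with a sum of 6511 RPM in primordial germ cells and 88580 in spermatogonia. let-7b-5p was 66.9-fold higher [61.1 to 73.3] and let-7f-5p 11.3-fold [11.1 to 11.4]. Lower in spermatogonia were all 14 members of the miR-290 cluster (median -4.87, below the random lists), from 42592 to 1692 RPM, with miR-295-3p 33.0-fold lower [31.9 to 34.1]. The miR-17/92 cluster and its paralogs, which promote proliferation, fell by at least 4-fold in 13 of 23 measured members (median -2.54), with miR-106a-5p 89.1-fold lower [78.6 to 101.4] and miR-18b-5p 321-fold [226 to 472]. miR-182-5p, on chromosome 6 at 30165918 to 30165992, fell from 27.98% to 3.52% of miRNA reads. miR-302b-3p had 120 reads in primordial germ cells and none in spermatogonia, at least 35.6-fold lower.

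The miRNA with the most reads in spermatogonia was miR-143-3p, of chromosome 18 at 61649196 to 61649258. It took 23.1% of miRNA reads and was 25.01-fold higher than in primordial germ cells [24.9 to 25.2]. miR-143 and miR-145a are miRNAs of smooth muscle and of the muscle-like peritubular cells of the testis, and miR-145a-5p was 73.5-fold higher [66.1 to 81.9]. Other markers of cells outside the germ line were higher in the same library, as endothelial miR-126a-3p was 7.61-fold [7.46 to 7.77] and erythroid miR-451a 13.0-fold [12.2 to 13.8]. The sum of the gonadal soma list was 15126 RPM against 1773, with 3 of 4 measured members at least 4-fold higher. Of that sum in spermatogonia, miR-202-5p alone made up 14472.5 RPM, and the list also summed to 6108 RPM in the oocyte. The neuronal sum, in contrast, was 137 against 3737 (median -2.68). The leukocyte sum was 304 against 588, although its 4 measured members had a median log2 ratio of 1.34, with 2 at least 4-fold higher and none 4-fold lower. miR-3470b and miR-3470a were 115-fold higher in spermatogonia, each with an interval from 111 to 119. Of the Dlk1-Dio3 cluster, an imprinted cluster on chromosome 12, 13 of 56 measured members were at least 4-fold higher (percentile 93.74) and miR-127-3p was 11.7-fold higher [11.5 to 11.9]. The Sfmbt2 cluster lay at -0.11 where the median of all miRNAs was 0.65 (percentile 0.92). The split of 67.0% higher among the miRNAs at least 4-fold apart evened out under other scalings, to 103 higher and 90 lower with TMM factors, 107 and 88 with DESeq2's and 98 and 98 with the deposited factor, at shifts of -0.64, -0.61 and -0.71.

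**Figure D3:**
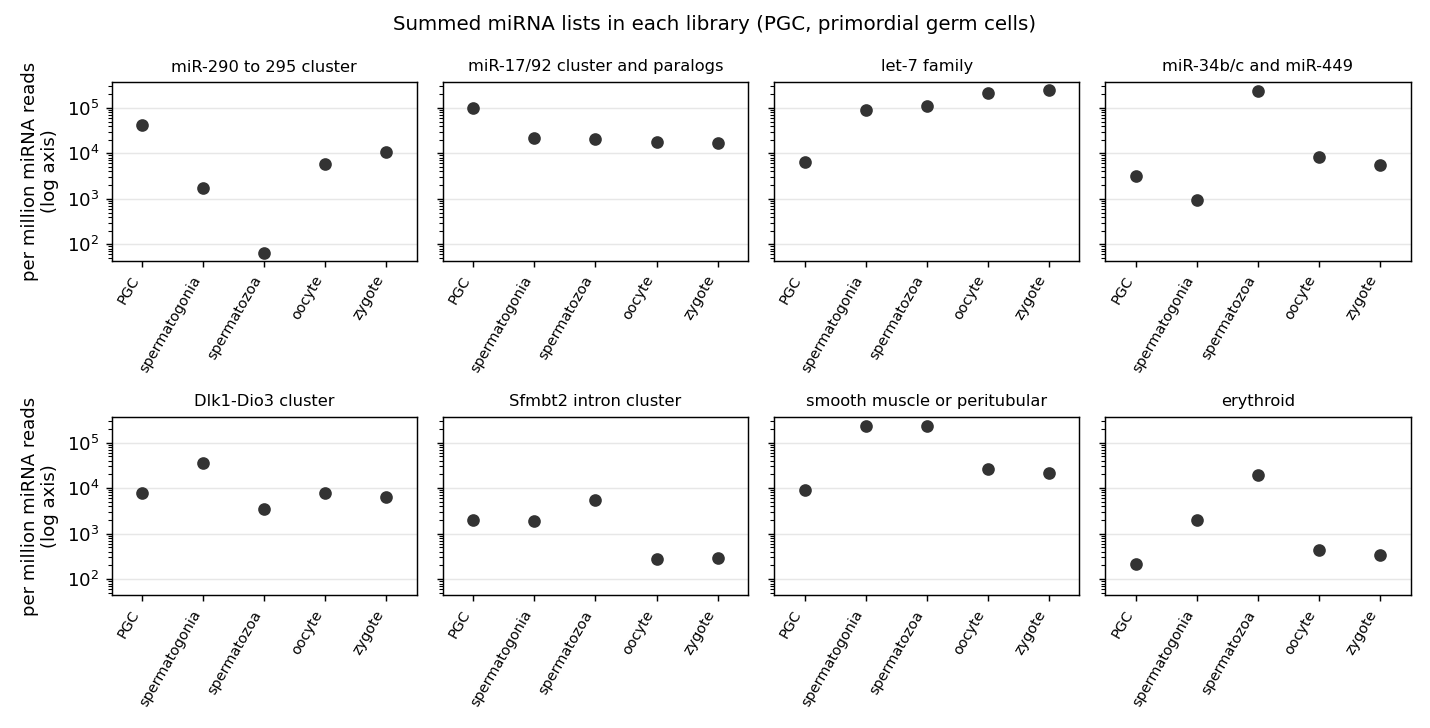
Points give the summed reads of 8 miRNA lists in RPM (log axis) in each of the 5 libraries, 1 point per library. The miR-34b/c and miR-449 list reaches 235995 in spermatozoa against 932 in spermatogonia, and the smooth muscle list 233111 in spermatogonia and 230783 in spermatozoa.

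From spermatogonia to spermatozoa, 14.9% of the measured miRNAs were at least 4-fold higher (70) and 37.2% at least 4-fold lower (175). All 5 measured members of the miR-34b/c and miR-449 list were higher (median 9.18, above the random lists), with miR-34c-5p 254-fold [249 to 259] and miR-34b-3p 831-fold [665.1 to 1053]. miR-466f-3p was 298-fold higher [242.3 to 369.3]. Of its 4 annotated precursors 3 lie in introns of Sfmbt2 on chromosome 2, and which precursor gave the reads is not known. Of 34 measured members of the Sfmbt2 cluster only 4 were at least 4-fold higher and 1 lower (median 0.18, percentile 97.48). Over all 4 classes these were 3 and 26. In the Dlk1-Dio3 cluster 35 of 46 measured members were at least 4-fold lower (median -3.70, or -3.29 with 0 reads set to 3 counts, percentile 0.02), and miR-127-3p was 34.6-fold lower [31.9 to 37.5]. miR-202-5p of the gonadal soma list was 146-fold lower [121.7 to 175.3], miR-3470a 259-fold [219 to 309] and miR-871-3p of the X-linked testis cluster 117-fold [104 to 131], although that cluster as a list lay at percentile 58.1. The miR-290 cluster was lower again in 9 of 9 measured members. With reads scaled to all 4 classes together, of which miRNAs are a small part in spermatozoa, the split was 18 higher and 358 lower, and with the deposited factor 25 and 312, at shifts of -2.86 and -2.13. It turned to 361 higher and 252 lower with a minimum of 1 read.

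In spermatozoa miR-143-3p again took 23.0% of miRNA reads, a spermatogonia to spermatozoa ratio of 1.003 [0.9988 to 1.007], while miR-145a-5p was 4.68-fold lower [4.31 to 5.10] and miR-126a-3p 35.5-fold lower [31.1 to 40.6]. miR-451a was 12.2-fold higher than in spermatogonia [12.0 to 12.5]. All 7 measured members of the miR-200 list, of epithelia such as that of the epididymis, were at least 4-fold higher (median 4.70, percentile 99.99), and so were 4 of 5 measured leukocyte members (median 3.56) and all 3 measured neuronal members (median 3.60). Over all 4 classes together, each of these ratios to spermatogonia is lower by 2.86 on the log2 scale.

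Among snoRNAs, SNORD60, a C/D box snoRNA, took 91.2% of snoRNA reads in primordial germ cells, 92.6% in spermatogonia, 88.1% in spermatozoa, 79.1% in the oocyte and 76.3% in the zygote. Its gene lies on chromosome 17 at 24528476 to 24528553, in an exon of the antisense transcript Rab26os. SNORD32, of the Rpl13a host gene, took 6.25% in spermatozoa and was 35.5-fold higher than in the oocyte [33.6 to 37.5] and 110-fold higher than in spermatogonia [105.6 to 113.8]. The Cajal body RNA scaRNA6 took 2.54% in the oocyte and 3.70% in the zygote, 290-fold above spermatozoa in the zygote [245 to 347]. SNORD64, of the imprinted Snrpn locus, had 596 reads in the zygote and 3 in spermatozoa, a ratio of 345 [118 to 1678]. Scaled to all 4 classes, SNORD32 was 96.4-fold higher in spermatozoa than in the oocyte and 26.6-fold higher than in spermatogonia, and scaRNA6 and SNORD64 were 84.4-fold and 100.2-fold higher in the zygote than in spermatozoa. H/ACA box snoRNAs summed to 1.65% of snoRNA reads in the zygote and 1.11% in the oocyte, against 0.164% in spermatozoa, 0.166% in spermatogonia and 0.146% in primordial germ cells. Over all 4 classes that order turned for the earlier male germ cells, with 0.0415% in primordial germ cells and 0.0322% in spermatogonia against 0.0226% in the zygote, 0.0192% in the oocyte and 0.0077% in spermatozoa. The C/D box sum was between 94.3% and 99.7% in the 5 libraries.

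The splits of the snoRNA comparisons moved with the scaling, while that of zygote and spermatozoa kept its larger side. Scaled to the snoRNA reads, 1 of 99 was at least 4-fold higher and 1 lower in the zygote than in the oocyte. There were 1 and 3 over all 4 classes, 1 and 2 with TMM or DESeq2 factors or without the 5 most abundant snoRNAs of each library in the totals, and 2 and 1 with the deposited factor. Against spermatozoa 48 were higher and 9 lower in the zygote, but 21 and 20 without those snoRNAs, 21 and 19 over all 4 classes, 24 and 14 with TMM and 22 and 16 with DESeq2 factors. Between spermatozoa and oocyte 8 were higher and 46 lower, but 19 and 17 without those snoRNAs, 19 and 22 over all 4 classes, 14 and 25 with TMM, 15 and 24 with DESeq2 and 13 and 26 with the deposited factor. Between spermatogonia and primordial germ cells 21 were higher and 4 lower, against 9 and 6 with TMM factors or over all 4 classes, 8 and 6 with DESeq2 factors and 6 and 14 with the deposited factor. Between spermatozoa and spermatogonia the split of 15 higher and 10 lower turned to 10 and 14 with TMM, 11 and 12 with DESeq2, 3 and 38 with the deposited factor, 8 and 19 without those snoRNAs, and 2 and 59 over all 4 classes. It was 27 and 28 with a minimum of 1 read.

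Among piRNAs, PIR64428 took 36.3% of reads in spermatozoa, 12.1% in spermatogonia, 10.7% in primordial germ cells and 1.77% in the zygote. It was 13.6-fold higher in spermatozoa than in the oocyte [13.6 to 13.7]. PIR75142 led the oocyte with 6.18%. Of 4170 piRNAs, 215 were at least 4-fold higher and 208 lower in the zygote than in the oocyte (91 and 403 over all 4 classes). Of 5039, 1797 were higher and 1698 lower in the zygote than in spermatozoa (1376 and 2553 over all 4 classes). Of 5354, 1693 were higher and 1889 lower in spermatozoa than in the oocyte (2343 and 1371). PIR227921 had 8687 reads in the zygote and none in spermatozoa, at least 5521-fold, while PIR24546 had 7516 in spermatozoa and none in the zygote, at least 1314-fold. Spermatogonia had 1896 of 6362 piRNAs at least 4-fold above primordial germ cells and 338 below, a split that was 1421 and 577 with TMM factors and 974 and 979 with DESeq2's size factors. In spermatozoa 1212 of 7071 were at least 4-fold above spermatogonia and 4237 below, which became 2368 above and 1818 below with DESeq2's size factors. TMM factors gave 1765 and 2699, the deposited factor 1879 and 2478, and all 4 classes together 1602 and 3095. Counting from 1 read, the split of spermatogonia and primordial germ cells was 21294 above and 21954 below.

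Endo-siRNA profiles of oocyte and zygote were close. mmur001272954 alone took 16.1% of endo-siRNA reads in the oocyte and 17.4% in the zygote, and was 405-fold lower in spermatozoa than in the zygote [374 to 440]. Of 33179 endo-siRNAs, 243 were at least 4-fold higher and 204 lower in the zygote than in the oocyte (1166 and 54 with the deposited factor, and 74.2% of the calls higher over all 4 classes, against 54.4%). Against spermatozoa, 18880 of 24086 were at least 4-fold higher in the zygote and 1469 lower. The spermatozoa table held 1370190 endo-siRNA reads against 30760735 in the zygote, so many of those ratios rest on few spermatozoal reads, and 7631 higher and 1319 lower had their whole counting interval beyond 4-fold. Likewise 1423 were higher and 16889 lower in spermatozoa than in the oocyte, of which 1302 and 7501 by the interval. Both splits turned with a minimum of 1 read, to 27524 higher and 64148 lower in the zygote than in spermatozoa, and to 58243 higher and 26549 lower in spermatozoa than in the oocyte. mmur000042018 led the spermatozoa table with 9.25% and primordial germ cells with 4.31%. In spermatogonia 3319 of 6188 were at least 4-fold above primordial germ cells and 834 below (4385 and 452 over all 4 classes), and in spermatozoa 932 of 6137 were above spermatogonia and 4616 below. At a minimum of 1 read these were 21002 and 21206, and 39294 and 27154.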

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

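The tests of this part were all chosen after the values they rest on had been seen. The 6 entries of the snoRNA files that name no snoRNA are outside the comparisons, and their sum had reads in each of the 5 libraries, although 1 of the 6 had 3 reads in the oocyte and none in the others. Their summed share of the file was 0.551% in primordial germ cells, 0.824% in spermatogonia, 0.896% in spermatozoa, 3.209% in the oocyte and 4.585% in the zygote, with no control library to set them against.

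The pattern weighed is miR-143-3p at 23.1% of miRNA reads in spermatogonia and 23.0% in spermatozoa. The marker lists were counted without the miR-143 arms, which the smooth muscle list holds. With those arms that list took 2.66% of miRNA reads in the oocyte, 2.10% in the zygote and 0.926% in primordial germ cells. In the oocyte nearly all of it was the miR-143 arms, so these were also present in a library freed of cumulus cells. Their source there was not tested, and miR-143 alone is thus not a sure marker of somatic testis cells. The same mixture of somatic testis cells in both libraries is argued against for spermatozoa, though on few miRNAs. The sums of 3 marker lists, endothelial, gonadal soma and smooth muscle, lay 24.1-fold, 84.4-fold and 4.59-fold below those in spermatogonia. At the shifts of DESeq2 factors (0.57) or of totals without the 5 most abundant entries of each library (0.36), smooth muscle is less than 4-fold below. Over all 4 classes each log2 ratio is lower by 2.86. By medians of log2 ratios, endothelial (-4.44) and gonadal soma (-4.10) lay at least 4-fold below spermatogonia, but the 2 measured smooth muscle miRNAs (-1.22) did not. The endothelial list holds only 2 miR-126 entries. Of 4 measured gonadal soma members 2, the arms of miR-202, were at least 4-fold lower and 1 was higher. The gonadal soma list also summed to 6108 RPM in the oocyte. For spermatogonia, somatic testis cells remain open. By sum and by median, 5 of 8 marker lists with reads were at least 4-fold above primordial germ cells. By sum, smooth muscle or peritubular was 73.6-fold, endothelial 8.61-fold and gonadal soma 8.53-fold above, and erythroid and striated muscle were the others. Leukocyte, epithelium and neuron were not by either. The test asked for all 8 lists, and lists of neurons and of epithelium as in the epididymis need not rise with testis cells, so it could not decide. The gonadal soma median (2.55) drops below 4-fold at the shifts of TMM (-0.64), DESeq2 (-0.61) and the deposited factor (-0.71). The adhesion step and the Fn1 check were meant to exclude such cells, and a few may have stayed. Blood and duct epithelium or muscle in the spermatozoa library could not be decided either: by sums 1 of 4 lists, erythroid at 45.4-fold, was at least 4-fold above the oocyte, with leukocyte, epithelium and smooth muscle at 2.20-fold, 2.31-fold and 2.11-fold. By medians of their members 3 of the 4 were, with log2 ratios of 5.68 for erythroid, 6.87 for leukocyte and 3.24 for epithelium, against 1.09 for the 1 measured smooth muscle miRNA. No value settles this, although the gradient and the shock were meant to remove such cells. Library and cell type coincide, so a germ cell difference between stages stays open and untested. The lists share no members, but the primordial germ cell library had reads on them too, from cells not known here: on 5 of 7 gonadal soma, 2 of 3 other smooth muscle and 2 of 2 endothelial miRNAs.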

How the results depend on the processing

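The deposited factor, runs counted once and the interval rule were alternatives chosen after the data were seen, and so was the rule that a split of counts is called reversed only where 1 side of the reported split held at least 1.5 times the other. Of 462 alternative values of the summary results, 334 were counted as stayed. Outside list medians, that meant within the counting interval, or within 1.5 times the count, without a reversal by that rule. A list median, of marker lists too, stayed if its sign and its standing apart or not from the random lists were unchanged. Scaling cannot change that standing by construction, so medians shifted by scaling without a change of sign are among those counted as stayed. A further 95 moved, 29 reversed, 3 lists came to stand apart and 1 no longer did. Of 960 values for single entries and marker lists, 712 stayed, 239 moved, 5 reversed, 3 came to stand apart and 1 no longer did. The floor of 3 reads was highest for miRNAs in spermatozoa (2.47 RPM), for snoRNAs in the zygote (5.07), and for piRNAs (0.515) and endo-siRNAs (2.47) in primordial germ cells. A minimum of 1 read admits entries whose ratio rests on a few reads. Lower minimums also compare more entries, so a count can move while its share of the entries compared stays. Scaling shifted the median log2 ratio of a comparison by between -2.86 and 0.96 for miRNAs, -2.04 and 1.61 for snoRNAs, -1.92 and 3.20 for piRNAs, and -3.72 and 4.51 for endo-siRNAs. The length and first base of reads and counting identical sequences once were not run. Except where a shift or a lower minimum is itself the change, the cause was not tested.

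Comparisons are written Z/O (zygote to oocyte), Z/S (zygote to spermatozoa), S/O (spermatozoa to oocyte), G/P (spermatogonia to primordial germ cells) and S/G (spermatozoa to spermatogonia). The numbers of entries at least 4-fold apart that changed by over 1.5 times, or whose larger side turned from at least 1.5 times the other (marked turned), were as follows. With the deposited factor, miRNA counts were 17 in Z/O. With the deposited factor, snoRNA counts were 20 in G/P (turned), 41 in S/G (turned). With the deposited factor, endo-siRNA counts were 1220 in Z/O. With a minimum of 20 reads, miRNA counts were 32 in Z/O, 259 in Z/S, 266 in S/O. With a minimum of 20 reads, snoRNA counts were 43 in G/P, 47 in S/G (turned). With a minimum of 20 reads, piRNA counts were 1605 in Z/O, 12759 in Z/S, 13513 in S/O, 7072 in G/P, 18676 in S/G. With a minimum of 20 reads, endo-siRNA counts were 1812 in Z/O, 34117 in Z/S, 32802 in S/O, 13156 in G/P, 17288 in S/G. With a minimum of 1 read, miRNA counts were 247 in Z/O, 630 in Z/S, 660 in S/O, 583 in G/P, 613 in S/G (turned). With a minimum of 1 read, snoRNA counts were 15 in Z/O, 98 in Z/S, 90 in S/O, 56 in G/P, 55 in S/G (turned). With a minimum of 1 read, piRNA counts were 19005 in Z/O, 55564 in Z/S, 66630 in S/O, 43248 in G/P (turned), 69693 in S/G. With a minimum of 1 read, endo-siRNA counts were 21304 in Z/O, 91672 in Z/S (turned), 84792 in S/O (turned), 42208 in G/P (turned), 66448 in S/G (turned). Scaled to all 4 classes, miRNA counts were 3.8e+02 in S/G (18 higher and 358 lower). Scaled to all 4 classes, snoRNA counts were 4 in Z/O, 15 in G/P, 61 in S/G (turned). With TMM factors, snoRNA counts were 15 in G/P, 24 in S/G (turned). With DESeq2 size factors, snoRNA counts were 14 in G/P, 23 in S/G (turned). With DESeq2 size factors, piRNA counts were 1953 in G/P (turned), 4186 in S/G (turned). Without the 5 most abundant entries of each library in the totals, snoRNA counts were 36 in S/O (turned), 27 in S/G (turned). With the whole counting interval beyond 4-fold, piRNA counts were 243 in Z/O. With the whole counting interval beyond 4-fold, endo-siRNA counts were 208 in Z/O, 8950 in Z/S, 8803 in S/O. With a pseudocount of 5, endo-siRNA counts were 7987 in Z/S, 7843 in S/O. From near-even splits the larger side changed in 27 values not marked, 20 of them among the 334. In 7 the sides, higher and lower, came to lie at least 1.5 times apart: for piRNAs over all 4 classes 91 and 403 in Z/O, 1376 and 2553 in Z/S and 2343 and 1371 in S/O, for piRNAs from 20 reads 5089 and 7670 in Z/S, and from 1 read 20225 and 35339 in Z/S and 49697 and 16933 in S/O, and for miRNAs from 1 read 211 and 419 in Z/S.

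Among list medians of log2 ratios, some changed sign or their place among the random lists. With DESeq2 size factors, the median was 0.43 for miR-17/92 cluster and paralogs in S/G, 0.46 for let-7 family in S/G, -0.22 for miR-34b/c and miR-449 in G/P, 0.019 for X-linked testis cluster in S/G, 0.003 for Dlk1-Dio3 cluster in Z/O, 0.12 for smooth muscle or peritubular in S/G. With a minimum of 20 reads, the median was -0.60 for miR-34b/c and miR-449 in Z/O (no longer apart), 1.62 for Dlk1-Dio3 cluster in Z/S (now apart), -1.51 for Dlk1-Dio3 cluster in S/O (now apart), 0.49 for Sfmbt2 intron cluster in S/G (now apart), -0.24 for leukocyte in G/P, -0.29 for striated muscle in S/G. With TMM factors, the median was -0.25 for miR-34b/c and miR-449 in G/P, 0.16 for X-linked testis cluster in Z/S, 0.052 for Dlk1-Dio3 cluster in Z/O. Scaled to all 4 classes, the median was 0.18 for Dlk1-Dio3 cluster in Z/O, -2.68 for Sfmbt2 intron cluster in S/G, -0.45 for erythroid in S/G, -1.25 for striated muscle in S/G.

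Class shares are in the order primordial germ cells, spermatogonia, spermatozoa, oocyte, zygote. Without the pooled set of the 5 most abundant entries of each class and library, miRNA took 45.7%, 36.4%, 4.71%, 2.01%, 2.35%. For snoRNA the shares were 1.15%, 0.694%, 0.283%, 0.198%, 0.174%. For piRNA the shares were 42.9%, 39.2%, 82.9%, 33.7%, 23.7%. For endo-siRNA the shares were 10.3%, 23.6%, 12.1%, 64.1%, 73.8%. With runs counted once, miRNA took 48.7%, 44.4%, 7.24%, 6.17%, 6.88%. For snoRNA the shares were 30.5%, 21.3%, 6.12%, 2.3%, 1.75%. For piRNA the shares were 16.7%, 22.1%, 79.3%, 27.3%, 18.6%. For endo-siRNA the shares were 4.12%, 12.2%, 7.39%, 64.2%, 72.8%.

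With a minimum of 20 reads, the Spearman correlation of the zygote was 0.945 with the oocyte over miRNAs, 0.558 with the spermatozoa over miRNAs, 0.942 with the oocyte over snoRNAs, 0.617 with the spermatozoa over snoRNAs, 0.854 with the oocyte over piRNAs, -0.239 with the spermatozoa over piRNAs, 0.915 with the oocyte over endo-siRNAs, -0.018 with the spermatozoa over endo-siRNAs. The Pearson correlation of the zygote was 0.967 with the oocyte over miRNAs, 0.476 with the spermatozoa over miRNAs, 0.503 with the spermatozoa over snoRNAs, 0.925 with the oocyte over piRNAs, -0.123 with the spermatozoa over piRNAs, 0.943 with the oocyte over endo-siRNAs, -0.148 with the spermatozoa over endo-siRNAs. With a 16-fold excess in place of 0 reads, 76.9% of spermatozoa-specific and 85.8% of control endo-siRNAs had a read in the zygote.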

Other observations

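The test of this part was chosen after the data were seen. The miR-302 cluster summed to 27.9 RPM in primordial germ cells, 1.72 in the zygote and 0 in the other libraries. The miR-30 family summed to 146380 RPM in the zygote and 90622 in the oocyte, and to 53770 in spermatozoa. Hepatocyte miR-122 had at most 4 reads in a library. Striated muscle miRNAs summed to 947 RPM in spermatozoa, 520 in the oocyte and 25.2 in primordial germ cells. snoRNAs of the Gas5 host gene summed to 0.302% of snoRNA reads in primordial germ cells, 0.101% in spermatogonia and 0.0454% in spermatozoa. They summed to 0.239% in the oocyte and 0.270% in the zygote. The Rpl13a host list summed to 7.48% in spermatozoa, 6.17% in primordial germ cells, 4.34% in spermatogonia, 2.53% in the oocyte and 1.73% in the zygote. These sums rest on different members. In spermatozoa SNORD32 took 6.25% and SNORD35 1.21%, but in primordial germ cells SNORD32 took 0.047% and SNORD35 6.10%. Over all 4 classes the list summed to 0.352% in spermatozoa and 1.75% in primordial germ cells. Of snoRNA reads, the small Cajal body list summed to 3.82% in the zygote and 0.0311% in spermatozoa. The Snrpn list summed to 0.0841% in the oocyte and 0.0003% in spermatozoa. The 1 measured snoRNA of the Dlk1-Dio3 locus took 0.0115% in spermatogonia and 0.0008% in spermatozoa.

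The piRNA entries fall into PIR and mmur names. PIR names took 72.3% of piRNA reads in spermatozoa, 60.9% in the zygote, 53.4% in the oocyte, 51.9% in spermatogonia and 50.8% in primordial germ cells. Of endo-siRNA reads in spermatozoa, 4.61% fell on names marked chrUn, against 0.289% to 0.420% in the other 4 libraries.

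One hypothesis was that sperm delivers miRNAs that raise their level in the zygote over the oocyte. The 28 miRNAs at least 16-fold higher in spermatozoa than in the oocyte had a median zygote minus oocyte log2 ratio of -0.175, and 35 control miRNAs enriched in spermatogonia or primordial germ cells one of -0.168. The difference was -0.007, with a bootstrap 95% interval over miRNAs from -0.594 to 0.377, so the hypothesis was neither borne out nor excluded. The 28 include members of the erythroid and leukocyte marker lists, among them miR-451a, miR-144-3p and miR-142-3p. miR-34c-5p stood at 8144 RPM in the oocyte and 5363 in the zygote.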
